A study of Drosophila melanogaster with 6 samples.

How the data were processed

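Total RNA from whole prepupae was labelled with biotin and hybridised to Affymetrix Drosophila Genome arrays, in which a probe set of short oligonucleotides reports 1 transcript or several. The deposited values are on a log2 scale and were made by RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, normalises between arrays and summarises each probe set, so absolute amounts of RNA per animal cannot be read from the values, and changes of dim or saturated transcripts are compressed. The genome build behind the array's design is not given in the sources used here. The column medians of the 6 arrays lay between 7.00 and 7.07 and the values between 3.45 and 15.43. No 2 arrays held identical values, correlations between arrays of a genotype were 0.993 to 0.996, and the highest between genotypes was 0.976.

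Samples were grouped by the genotype in their labels, with 3 arrays for the sox14 mutant and 3 for the w1118 control. Of 18952 probe sets, 183 Affymetrix control probe sets were left out of the tests. Of the 18769 tested, 13646 had 1 gene in the platform annotation, 402 had several and 4721 had none. Of these, 13543 probe sets were matched by gene identifier to the RefSeq annotation of the assembly Release 6 plus ISO1 MT, which changed 0 symbols and was used for names, neighbours and positions of genes. For 11981 genes the probe set with the highest mean was taken. Of the 1094 genes with more than 1 probe set, 10 had probe sets called in opposite directions. Members of the lists with no single-gene probe set were not analysed here.

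The genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Every adjusted p given for a gene comes from this fit. Gene lists were tested with limma's camera at a preset correlation of 0.01 on 1 probe set per gene, 2-sided, adjusted over 36 lists, and again with a correlation estimated from the data. The test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Sox14 and its nearest measured genes, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and up to 4 called members of each list, or 2 members where none was called. The wildcard of the P450 list also took the cyclophilin genes Cyp1 and Cyp40.

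Positions were tested with 2-sided Fisher's exact tests, and 3' minus 5' differences of control probe sets with exact permutation tests, whose smallest p is 0.1 for 3 against 3 arrays. On simulated data with the means and spread of these arrays, the fit recovered 32% of planted log2 changes of 0.5, 86% of 1, 96% of 2 and 100% of 3, and 3.09% of its calls were false. The list test gave p under 0.05 for 3.4% of simulated lists with no change. The simulated probe sets varied independently of each other. That share therefore says nothing about lists whose members vary together.

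The alternatives were a replicate block, median centring, quantile normalisation, a trended robust variance, array weights, a filter on the dimmest 40% of probe sets, the mean of a gene's probe sets, each array left out in turn, genes near Sox14 left out, a threshold of 0.01, other windows around Sox14 and an estimated correlation. Added after seeing the data were the P450 list without the cyclophilins, the midgut list with only probe sets designed to be specific to 1 gene, families of genes that share the leading letters of their symbols, genes changed over 4-fold with circular shifts along the genome, and list counts without the first mutant array. The arrays' low range, the lower 95% of AFFX-Dm control probe sets without the 2 that were higher in the mutant, was also set after seeing the data. So was the actin 3' minus 5' difference with each array left out.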

Results

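Gene expression was measured in whole Drosophila melanogaster prepupae collected at 0 h, immediately after pupariation, when the larva becomes immobile and metamorphosis begins. Animals homozygous for the L1 allele of Sox14, which encodes a transcription factor with an HMG-box DNA-binding domain, were compared with animals of the w1118 strain in whose background the allele was kept. Each of the 6 arrays held RNA pooled from 10 prepupae, with 3 arrays per genotype. All changes are mutant minus control on the log2 scale with their standard error, and group levels are means ± SD of log2 values over 3 arrays. The number of arrays limits the precision. The labels do not say whether the 3 samples of a genotype came from separate cultures, so the p-values measure the spread between these samples.

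Sox14 itself was lower in the mutant. Its probe set read 10.58 ± 0.21 in the mutant and 11.57 ± 0.16 in the control, so it fell by 0.99 ± 0.13 (adjusted p = 0.00101), and the 3 mutant arrays all lay below the 3 control arrays. The probe set therefore still read at a high level in the mutant. It is of a type named as shared, although the annotation gives it a single gene, and whether other transcripts add to its signal was not tested. Where the lesion of the allele lies relative to this probe set is not given in the sources used here. Of the nearest measured genes on chromosome arm 2R, Phm, which encodes an enzyme that amidates neuropeptides, rose by 0.44 ± 0.09 (adjusted p = 0.00797) in the brighter of its 2 probe sets, with the other not called (adjusted p = 0.126), and PPP1R15 read 0.26 ± 0.09 higher without passing the test (adjusted p = 0.0826).

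The comparison of the genotypes asked which transcripts depend on Sox14 at the onset of metamorphosis. Among the 12 largest rises in the mutant were 2 trypsin, 2 Bomanin and 2 cytochrome P450 genes. All of these lie on 2R, the chromosome arm of Sox14. For them, strain differences linked to Sox14 cannot be told apart from an effect of Sox14. The same holds for the other changed genes on chromosome 2. More members rose than fell in the lists of midgut, muscle and detoxification genes, and more fell than rose in the list of autophagy genes. These lists were among the 10 of 36 called with camera's preset correlation, and none of the 36 was called with an estimated correlation. Of 18769 probe sets tested, 3577 were called at an adjusted p under 0.05 in limma, 1621 of them higher in the mutant and 1956 lower. With 1 probe set per gene, 24.7% of 11981 genes were called, 1354 higher and 1605 lower. Counts of list members called are to be read against that share. A change of more than 2-fold was seen for 521 higher and 370 lower probe sets, and of more than 4-fold for 181 and 67. The median change over all probe sets was -0.03, and the median SD between replicates was 0.112 in the mutant and 0.129 in the control. The 2 genotypes did not overlap for 36.2% of probe sets, where chance gives 10%.

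The first mutant array stood apart in its control probe sets. Its 18S rRNA probe sets averaged 12.18, against 7.56 to 7.94 on the other 5 arrays, and its 3' minus 5' difference for actin was 1.77, against 0.54 to 0.88. The actin difference was 0.42 larger in the mutant group (2-sided exact permutation p = 0.2) and 0.11 larger without that array. For eIF-4a it was 0.24 larger (exact p = 0.7) and for GAPDH 0.04 larger (exact p = 1), and without that array these differences were -0.03 and -0.13. The poly-A control probe sets averaged 0.36 higher in the mutant group, with all 3 mutant arrays above the controls (exact p = 0.1, the smallest that 3 against 3 arrays allow). Without the first mutant array 2751 probe sets were called, of which 2611 were also called in the same direction with all 6 arrays.

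**Figure D1:**
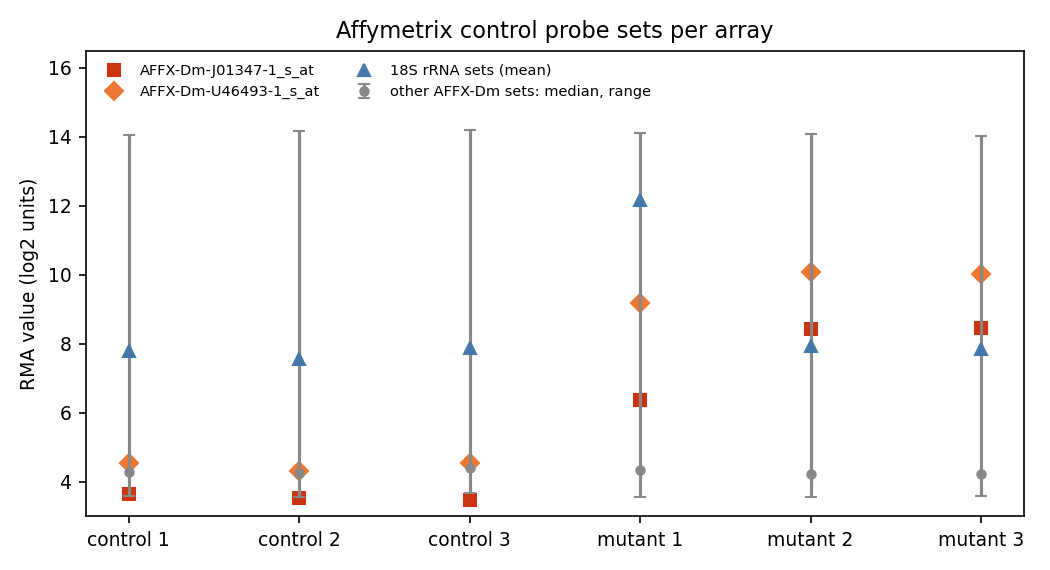
RMA values in log2 units (vertical axis) of Affymetrix control probe sets on each array: the mean of the 18S rRNA sets (triangles), 2 AFFX-Dm sets that were higher in the mutant (square and diamond), and the median and range of the other 98 AFFX-Dm sets (grey). The 18S rRNA sets reach 12.18 on the first mutant array and at most 7.94 elsewhere, and the 2 AFFX-Dm sets lie at 6.37 or above in the mutant and at 4.54 or below in the control.

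The 12 largest rises lay between 4.77 and 6.78. The trypsin gene epsilonTry rose by 6.66 ± 0.19, from 6.71 ± 0.22 to 13.37 ± 0.37, and betaTry by 5.82 ± 0.17. The Bomanins, short peptides secreted in the immune response through Toll, gave BomS2 with a rise of 6.78 ± 0.87 and BomT2 with 5.88 ± 0.36. BomS2 varied between control arrays (6.18 ± 2.07), and its 12.96 ± 0.65 in the mutant lay above all 3. Its change was 7.98 without the first control array, 6.15 without the third and 5.87 with array weights. The cytochrome P450 genes Cyp6g1 and Cyp4p1 rose by 6.66 ± 0.26 and 5.34 ± 0.12, and the neprilysin-like gene Nepl20 by 5.37 ± 0.18. The other genes among the 12 largest rises were CG5246 (5.73), CG11893 (5.68), CG32023 (5.16), CG10943 (4.78) and the Jonah protease gene Jon44E (4.77). Like the trypsin, Bomanin and P450 genes, Jon44E lies on 2R. CG5246, CG11893 and Nepl20 lie on 3R, and CG32023 and CG10943 on 3L. The adjusted p-values of the 12 in limma were at most 0.000825, the value of BomS2.

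The largest fall was in CG13962, which went from 13.72 ± 0.09 in the control to 7.25 ± 0.28 in the mutant, a change of -6.47 ± 0.14 (adjusted p = 1.85e-07). The cytochrome P450 gene Cyp6d2 fell by 4.58 ± 0.15, CG11865 by 4.14 ± 0.15 and CG9903 by 4.05 ± 0.12. CG13907 (-3.95 ± 0.19), Nt5a (-3.63 ± 0.10) and Taz (-3.50 ± 0.11), the gene of a cardiolipin-remodelling enzyme of mitochondria, came next. CG3649 (-3.48), CG17110 (-3.47), CG30148 (-3.47), CG43085 (-3.38) and tbc (-3.30) completed the 12 largest falls, all with adjusted p-values of 1.49e-05 or lower. Of these 12, CG13962 and CG11865 lie on 2L, and Cyp6d2, Taz, CG3649 and CG30148 on 2R. For them too, differences carried on the mutant second chromosome cannot be told apart from an effect of Sox14. CG9903 and tbc lie on the X, CG13907, Nt5a and CG43085 on 3L, and CG17110 on 3R. The sizes given for CG11893 among the rises and for CG11865, CG3649, CG30148 and tbc among the falls are minimum sizes. On all 3 arrays of their dimmer group these genes lay within the lower 95% of the other 98 AFFX-Dm control probe sets, below 5.73 to 5.99 depending on the array, where RMA compresses changes. The same holds for the sizes of the changes in Mal-A1, GstD5, Cyp6a17, Jhe, sNPF, Osi15 and Vha100-4 given below. The sizes for BomS2, BomT2 and Act88F, with 2 of 3 control arrays in that range, and for Eig71Ei, with 2 of 3 mutant arrays in it, are uncertain for the same reason.

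**Figure D2:**
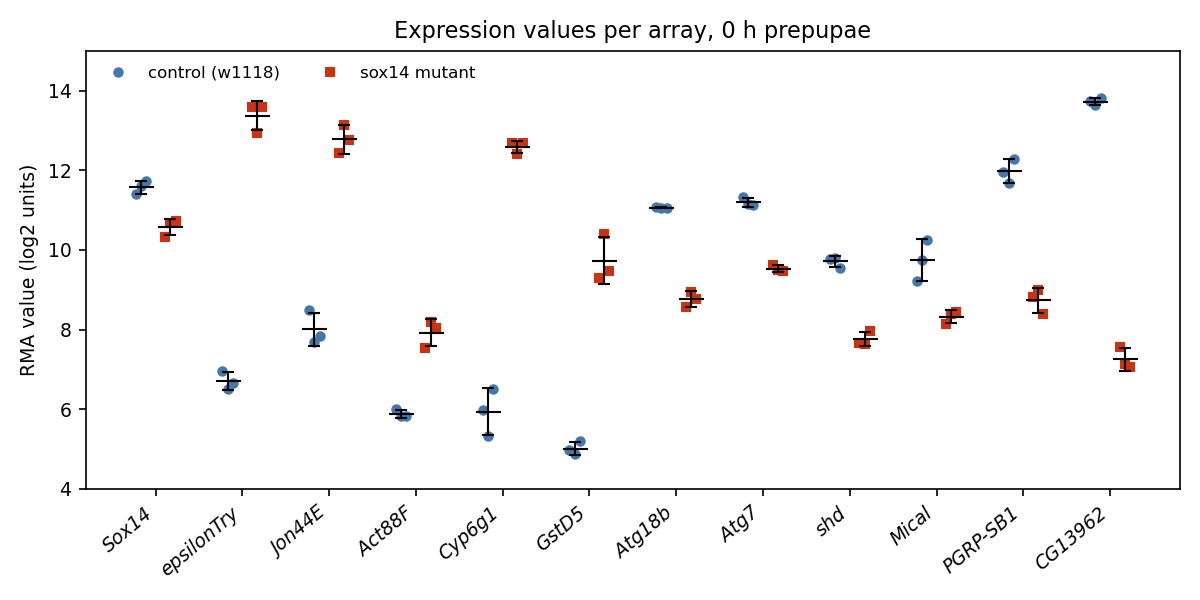
RMA values in log2 units (vertical axis) of 12 genes on each of the 6 arrays, with circles for the 3 control arrays and squares for the 3 mutant arrays; horizontal bars are means and error bars are SD (n = 3). Sox14, Atg18b, Atg7, shd, Mical, PGRP-SB1 and CG13962 are lower on every mutant array than on any control array, and epsilonTry, Jon44E, Act88F, Cyp6g1 and GstD5 are higher.

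Digestive enzymes of the midgut were higher as a group. Of 31 measured members, 18 rose and 2 fell (19 and 4 adjusted over the list alone), with a median change of 0.87. The list test gave an adjusted p = 1.71e-08 with a preset correlation, and adjusted p = 0.563 with an estimated correlation. Beside the trypsins and Jon44E, the maltase gene Mal-A1 rose by 2.83 ± 0.15. The 2 that fell, Jon25Biii (-1.24 ± 0.29) and Jon25Bii (-0.60 ± 0.18), were named after their values were seen. Of the 24 genes for tracheal, peritrophic matrix and mucin proteins, 7 rose and 1 fell, Mur89F (-0.61 ± 0.13, named after its value was seen). Adjusted over the list alone the counts were 9 and 1, and the list test gave an adjusted p = 0.0248, and adjusted p = 0.569 with an estimated correlation. Muc55B rose by 2.09 ± 0.20 and Muc18B by 1.92 ± 0.11. The list was no longer called without the third control array (adjusted p = 0.0529) or with array weights (0.0826).

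Structural genes of muscle were also higher. Of 17 measured, 12 rose and none fell (12 and 0 adjusted over the list alone; adjusted p = 4.29e-08, and adjusted p = 0.109 with an estimated correlation), with a median change of 1.19. The actin gene of the indirect flight muscle, Act88F, rose by 2.04 ± 0.16, bt, which encodes the giant protein projectin, by 2.02 ± 0.17, and the tropomyosin gene Tm2 by 1.88 ± 0.12. The muscle LIM protein gene Mlp60A rose by 1.75 ± 0.13 in its brightest probe set, while its other 2, dimmer, probe sets were not called.

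Enzymes that act on foreign and endogenous small molecules moved in both directions, with more rises than falls. Of 69 glutathione transferase and glucuronosyltransferase genes, 27 rose and 6 fell (29 and 9 adjusted over the list alone; adjusted p = 0.000716, and adjusted p = 0.600 with an estimated correlation). GstD5 rose by 4.71 ± 0.26, GstD4 by 4.02 ± 0.15 and GstE3 by 2.91 ± 0.17, while Ugt37D1 fell by 2.85 ± 0.13. Of 83 genes in the cytochrome P450 list, 24 rose and 9 fell (25 and 11 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.630 with an estimated correlation). Beside Cyp6g1 and Cyp4p1, Cyp6a17 rose by 3.84 ± 0.21. The P450 list was no longer called without the second control array (adjusted p = 0.0546).

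Among 6 measured heat shock genes, Hsp68 rose by 2.54 ± 0.10 and stv, which encodes a co-chaperone, by 0.95 ± 0.10, and none fell (3 and 1 adjusted over the list alone). The listed Hsp70 genes and Hsp83 had no single-gene probe set and are not covered. The list test gave an adjusted p = 0.0448, and adjusted p = 0.563 with an estimated correlation. Its call was lost without the second mutant array (0.0656), the first control array (0.0618) or the second control array (0.0546), and with the dimmest 40% of probe sets left out (0.0671).

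Autophagy genes were lower as a group. Of 24 measured, 14 fell and 2 rose (15 and 2 adjusted over the list alone; adjusted p = 0.000188, and adjusted p = 0.563 with an estimated correlation), with a median change of -0.52. Atg18b fell by 2.29 ± 0.11, Atg7, which encodes the E1-like enzyme of the autophagy conjugation systems, by 1.67 ± 0.10, the membrane protein gene Atg9 by 1.31 ± 0.10 and Atg18a by 1.30 ± 0.10. The 2 that rose, named after their values were seen, were ref(2)P (0.91 ± 0.14), whose protein is itself a cargo receptor degraded by autophagy, and Atg101 (0.39 ± 0.10).

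The other 3 lists called lower had medians of -0.25 for cell cycle genes, -0.27 for oxidative phosphorylation and -0.75 for late puff genes. Of 17 cell cycle and DNA replication genes, 4 fell and none rose (8 and 0 adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.569 with an estimated correlation): the mitotic cyclin genes CycB (-0.78 ± 0.11) and CycB3 (-0.65 ± 0.16), the kinase gene aurB (-0.71 ± 0.10) and Mcm3 (-0.60 ± 0.11). Of 19 genes of oxidative phosphorylation and the citrate cycle, 7 fell and none rose (8 and 0 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.569 with an estimated correlation). ND-75 fell by 0.57 ± 0.14 and ATPsynD by 0.43 ± 0.10, and without the first mutant array only 1 of the 19 was called, although the list test was still called. Of 9 late puff genes at 71E, which respond to ecdysone in the salivary gland, 3 fell and none rose (5 and 0 adjusted over the list alone; adjusted p = 0.0224, and adjusted p = 0.617 with an estimated correlation). These were Eig71Ei (-2.22 ± 0.58), Eig71Ef (-1.16 ± 0.23) and Eig71Ek, which was too dim in both groups for a size to be given, and the list was no longer called without the second mutant array (0.0618) or with the dimmest 40% of probe sets left out (0.0975). Of the 9, 5 fell without the first mutant array.

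**Figure D3:**
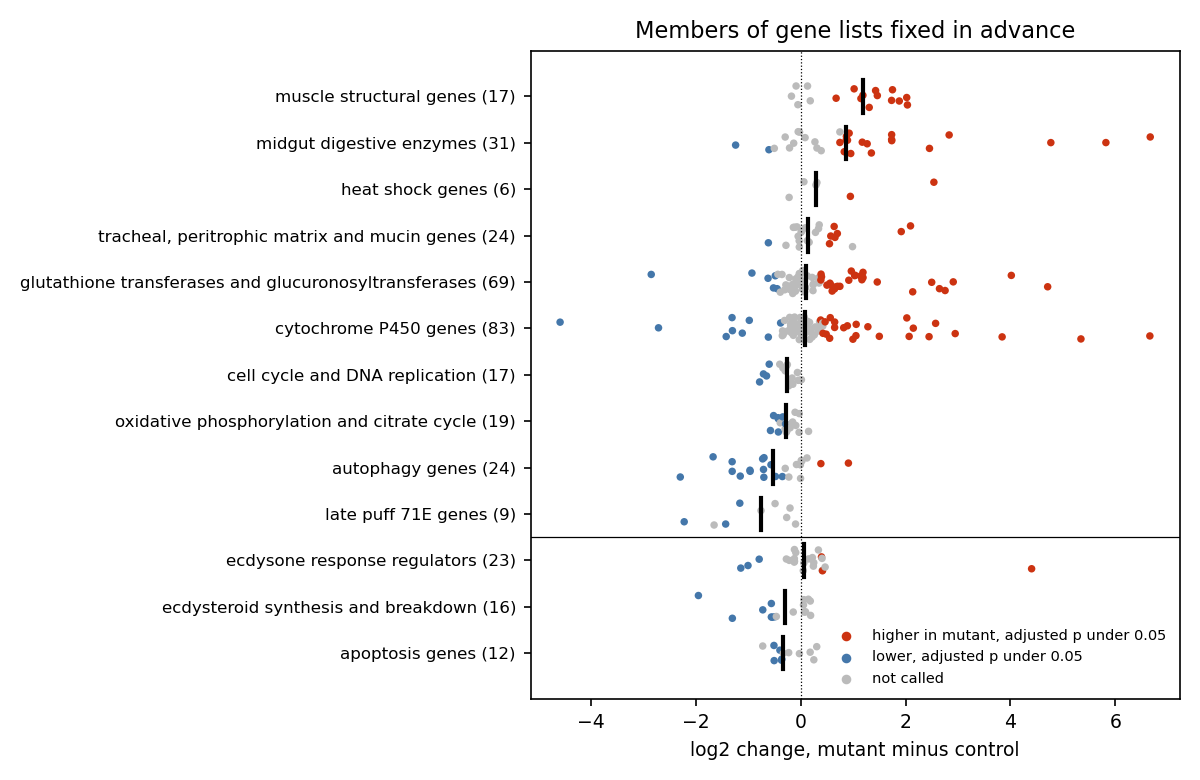
Log2 change, mutant minus control (horizontal axis), of each measured member of 13 gene lists fixed in advance, with the number measured in brackets; coloured points were called at an adjusted p under 0.05, grey points were not, vertical spread is only for display, and black bars are list medians. Above the line are the 10 lists called with the preset correlation, from a median of 1.19 for muscle to -0.75 for the 71E late puff genes; the 3 below the line were not called.

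Calls of some single genes in these and the following lists were lost when arrays were left out in turn. Those of dib, Debcl and ATPsynD were each lost with any of 5 arrays left out, and that of Eip78C with only 1. With at least 1 array left out, no call was made for CycB3, ND-75, ATPsynD, Eig71Ei, dib, Eip78C, Dronc, Strica, Buffy, Debcl, Rpn1, PGRP-SC2, Lcp65Ac, Sgs4 or Sox15. Eig71Ei read -2.84 without the first mutant array, and Sgs4 2.74 without the second. The means of the probe sets of Mmp2, whd and Mlp60A changed by 0.66, 0.74 and 0.54, less than their brightest probe sets.

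In all, 10 of 36 lists were called with camera's preset correlation, 6 higher and 4 lower. With an estimated correlation none was called, and 2 lists had an unadjusted p under 0.05. All 10 remained called in the same direction without the first mutant array.

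The lists of genes of ecdysone, the steroid that triggers metamorphosis, were not called with all 6 arrays. Of 16 genes for ecdysteroid synthesis and breakdown, 7 fell and none rose (7 and 0 adjusted over the list alone; adjusted p = 0.0526). The list was called lower without the second mutant array (0.0459), the third mutant array (0.0449) or the second control array (0.0281). The gene of the enzyme that makes 20-hydroxyecdysone, shd, fell by 1.95 ± 0.12, and its second probe set fell too. ecd fell by 1.30 ± 0.12, the sterol transport gene Npc1a by 0.72 ± 0.10 and the Halloween gene dib by 0.56 ± 0.17. Of 23 ecdysone response regulators, 3 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.548). The cyclin-dependent kinase gene Eip63E rose by 4.40 ± 0.29, while the nuclear receptor genes Eip78C (-1.14 ± 0.26), Hr78 (-0.79 ± 0.10) and usp fell. For usp, whose protein is the partner of the ecdysone receptor, the level was 8.22 ± 0.11 in the mutant and 9.23 ± 0.16 in the control. Eip74EF, Eip75B and crol had no single-gene probe set, so the list of response regulators does not cover them.

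Lists of tissue remodelling genes were not called with all 6 arrays. Of 12 dendrite pruning genes, 2 fell and none rose (2 and 0 adjusted over the list alone; adjusted p = 0.622). They were Mical, which is required for the pruning of sensory dendrites (-1.42 ± 0.23, with both probe sets called), and the microtubule-severing gene Kat60 (-0.45 ± 0.10). Of 12 apoptosis genes, 5 fell and none rose (7 and 1 adjusted over the list alone; adjusted p = 0.158), among them the initiator caspase gene Dronc (-0.39 ± 0.09), Strica (-0.50 ± 0.12), Buffy (-0.51 ± 0.13) and Debcl (-0.36 ± 0.09). Only 3 fell without the first mutant array. The apoptosis list does not cover rpr, hid, Drice or Diap1, which had no single-gene probe set. Of 11 disc morphogenesis genes, 2 rose (2 and 0 adjusted over the list alone; adjusted p = 0.0844): the matrix metalloprotease gene Mmp2 (9.83 ± 0.48 in the mutant and 8.33 ± 0.32 in the control, brighter of its 2 probe sets, the other not called) and ImpL2 (0.96 ± 0.16). The disc list was called higher without the first (0.0381) or the third mutant array (0.0449) and with array weights (0.0448). Of 41 proteasome genes, 7 fell and none rose (7 and 0 adjusted over the list alone; adjusted p = 0.162), with Rpn1 at -0.64 ± 0.15, and that list was called lower without the third mutant array (0.0449).

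Lists of nervous system, endocrine, blood cell and immune genes were not called with all 6 arrays. Of 17 neuronal genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0526), led by Snap25 (1.34 ± 0.13). Without the first mutant array 2 rose and 0 fell, and the list was called higher without the third mutant array (0.0273) and with array weights (0.0386). Of 18 neuropeptide and ecdysis hormone genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0606), led by sNPF (1.68 ± 0.20) and Dh31 (1.15 ± 0.10). Without the first mutant array 2 rose and 0 fell. The neuropeptide list was called higher without the third mutant array (0.0392) or the third control array (0.0340), and with the replicate block (0.0487). Of 9 juvenile hormone genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.622), with the esterase gene Jhe at -1.43 ± 0.12. Of 13 hemocyte and phenoloxidase genes, 3 rose and 1 fell (4 and 3 adjusted over the list alone; adjusted p = 0.842), among them eater (1.48 ± 0.12) and PPO1 (-0.75 ± 0.14). Of 11 genes for antimicrobial peptides and immune recognition, 2 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.622). BomS2 rose, whereas PGRP-SB1 (-3.24 ± 0.19), Def (-2.48 ± 0.31) and PGRP-SC2 (-1.06 ± 0.26) fell.

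Cuticle and secretion lists were not called. Of 66 Cpr cuticle genes, 9 rose and 6 fell (9 and 6 adjusted over the list alone; adjusted p = 0.557), with Cpr65Ec at 1.32 ± 0.15 and Cpr56F at -1.28 ± 0.13. Of 9 larval cuticle genes, 1 rose, Lcp65Ac (1.03 ± 0.28), and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.809). None of 10 prepupal and pupal cuticle genes was called, also over the list alone (adjusted p = 0.622); Edg91 read 0.31 ± 0.10. Of 24 Tweedle genes, 2 rose, or 1 without the first mutant array, and none fell (2 and 0 adjusted over the list alone; adjusted p = 0.750). Of 24 Osiris genes only Osi15 rose, by 1.37 ± 0.15 (1 and 0 adjusted over the list alone; adjusted p = 0.828). Of 28 chitin genes, 5 rose and 5 fell (6 and 6 adjusted over the list alone; adjusted p = 0.566), with the chitinase gene Cht4 at 2.30 ± 0.23 and Idgf5 at -3.10 ± 0.21. Of 12 salivary glue genes, Sgs4 rose by 2.03 ± 0.53 and Pig1 fell by 0.83 ± 0.14 (1 and 1 adjusted over the list alone; adjusted p = 0.645). The rise of Sgs4 was not called with any of 4 arrays left out, the first mutant array among them.

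The remaining metabolic and housekeeping lists were not called. Fewer of their members were called without the first mutant array: 2 lipid genes rose, 0 fat body genes rose, 0 glycolysis genes fell, 4 lysosomal genes fell, 0 ribosomal protein genes fell and 1 Sox family gene fell. Of 15 lipid genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.548), with whd at 1.69 ± 0.10 in its brighter probe set, the other not called, and the lipase gene mag at 1.53 ± 0.19. Of 8 fat body storage and hemolymph genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.382), with the lipid droplet gene Lsd-1 at -1.03 ± 0.17 and Fbp2 at -0.86 ± 0.11. The size for Fbp2 is a minimum, since its control values (15.25 to 15.35) lay close to the highest on those arrays (15.38 to 15.43). Of 10 glycolysis genes, Hex-A rose by 0.82 ± 0.14 and 4 fell (2 and 7 adjusted over the list alone; adjusted p = 0.340). Of 37 lysosomal genes, 6 rose and 7 fell (9 and 11 adjusted over the list alone; adjusted p = 0.905), among them Vha100-4 (1.23 ± 0.15) and Npc2b (-0.90 ± 0.14). Of 40 cytosolic ribosomal protein genes, 1 rose and 1 fell (0 and 0 adjusted over the list alone; adjusted p = 0.162). Of 8 Sox family genes, Sox14 and Sox15 (-0.34 ± 0.08) fell and none rose (3 and 1 adjusted over the list alone; adjusted p = 0.162). A second, dimmer Sox15 probe set was not called (-0.14 ± 0.10, adjusted p = 0.401).

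Lists of markers of the male germ line and of sex were not called with all 6 arrays. Of 22 testis genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.548), with Mst84Db at 1.29 ± 0.17 and nht at -0.79 ± 0.14. Without the first mutant array 1 rose and 1 fell, and the list was called higher without the second control array (0.0246). None of 7 dosage compensation and sex marker genes was called, also over the list alone (adjusted p = 0.809), and Sxl read 0.38 ± 0.14. The median and the direction of the test had opposite signs for the Cpr, Tweedle, Osiris, sex marker, hemocyte and lysosomal lists, with medians below 0 and a test towards higher values. For the immune list the median was -0.28, the mean 0.08 and the test towards lower values.

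The chromosomal positions of the called genes were compared because the mutant chromosome may carry differences from the control strain near Sox14. Of 486 measured genes within 2 Mb of Sox14, 26.1% were called, against 24.8% elsewhere (odds ratio 1.07, 2-sided Fisher's exact p = 0.486). On the whole of arm 2R 28.0% of 2426 genes were called (odds ratio 1.23, adjusted p = 0.000346 over 7 Fisher's exact tests). On the X 21.3% of 1873 genes were called (odds ratio 0.792, adjusted p = 0.000370 by the same exact tests), and with the dimmest 40% of genes left out the odds ratio on the X was 0.913 (exact p = 0.221). Neighbouring genes are not independent in these tests.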

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

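Both tests of these control probe sets were chosen after their values were seen. A pair of Affymetrix control probe sets, outside the tested genes, stood above the control samples in every mutant sample. AFFX-Dm-U46493-1_s_at was 5.31 higher in the mutant (9.77 ± 0.51 against 4.46 ± 0.13), and AFFX-Dm-J01347-1_s_at was 4.20 higher (6.37, 8.43 and 8.46 against 3.64, 3.53 and 3.48). What these probe sets target is not given in the sources used here. Of the probe sets that share the J01347 prefix, 3 others changed by -0.05, 0.06 and 0.29 and were not called. All 98 other AFFX-Dm control probe sets had a median change of -0.054 and a range of -0.34 to 0.29, which argues against a general rise from background or scaling. The lowest mutant value lay 2.72 above the highest control value of the same probe set, but this gap is what singled the sets out and says nothing about its source. Whether a construct in the mutant stock carries these sequences stays open, and no biological explanation was tested.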

How the results depend on the processing

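Alternatives chosen after seeing the data were the changed P450 and midgut lists, gene families, genes over 4-fold and list counts without the first mutant array. The actin difference with each array left out and the low range of the arrays were also chosen then. The others in this section were planned. At an adjusted p under 0.01, 1963 probe sets were called, 963 higher and 1000 lower, because the threshold is stricter. With an estimated correlation 0 lists were called higher and 0 lower, since that setting widens the test. The odds ratio on the X was 0.913 with the dimmest 40% of genes left out; the cause was not tested. Leaving out 1 array at a time gave 2493 (without the second mutant array) to 3268 called probe sets, 5 to 9 lists higher and 4 to 6 lower. The change of Sox14 ranged from -1.08 to -0.87, and the actin 3' minus 5' difference from 0.11 to 0.61. No label says that the replicate numbers pair the samples. The correlations of deviations from the group means were 0.173, -0.101 and -0.023 for the same numbers. For unlike numbers they ranged from -0.264 to 0.259, so these values do not settle whether samples were paired. With the replicate number as a block 3276 probe sets were called, 3076 of them shared with the unblocked fit, and the neuropeptide list was called (adjusted p = 0.0487). Median centring gave 3848 calls, 37.9% of them higher against 45.3% as deposited, with a median change of -0.07.

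Of the 133 called named genes, 38 lost their call under some alternative, 15 to 29 of them with a given array left out and 13 with the replicate block. Over all 1898 values, 172 lost a call, 2 gained one and 0 reversed, and none of the 24 largest rises and falls lost its call. Of 612 list values 19 lost and 13 gained a call. The P450 list without the cyclophilins and the midgut list of specific probe sets were still called. Signal over background limits 20 called named genes, 4 of them in both groups.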

Other observations

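The tests of infection, of chromosome 2, of midgut share, and of gene families were chosen after results were seen, as were the genes named here; the tests of chance, RNA degradation and cross-hybridisation were set before their results were seen, but a condition was added to the last of them afterwards. Among 127 families of genes that share the leading letters of their symbols, 8 were called, and the Bomanin family had 6 of 8 genes risen and none fallen, with a median change of 3.13 (adjusted p = 0.00354, and adjusted p = 0.891 with an estimated correlation). BomS5 rose by 4.38 ± 0.91 and BomBc2 by 3.81 ± 0.44, and BomS5 varied between control arrays (6.76 ± 1.95). The first mutant array was the highest mutant array for all 6, and without it 5 rose and BomBc2 changed by 3.20, BomS5 by 3.74 and BomS4 by 1.73 (2.46 with all arrays). BomS5 changed by 5.49 without the first control array and 3.63 without the second. Without the third control array only 3 of the 8 were called, with BomS5 and BomS4 no longer among them. The sizes for BomBc2 and BomS4 are minimum sizes, since all 3 control arrays lay in the low range of the control probe sets. All 7 measured members of the immune list that belong to the Imd pathway read below 0, with a median of -1.06, and 3 of them fell (2 to 4 with each array left out). These values were seen before the test was set. They run against an infection that raised all measured induced immune genes alike. AttA, AttB, AttC, CecA1, CecA2, CecC and Dro of the immune list had no single-gene probe set and are not covered. An infection or other cause acting on the Bomanins, or on Toll-induced genes more widely, without the Imd members was not tested and stays open. BomS2 and BomT2 lie on 2R, so strain differences linked to Sox14 stay open for them too.

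The other called families were Mal, Atg, Gst, Jon, Muc, Snx and Cyp, of which all but Snx largely repeat the fixed lists. Of 7 sorting nexin genes (Snx), 3 fell and none rose (median -0.32, adjusted p = 0.0300). Every called family had an adjusted p = 0.891 with an estimated correlation.

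The midgut enzymes may be higher because the mutant samples held more midgut RNA, or because the enzymes' genes themselves changed. For epsilonTry, betaTry and Jon44E, which lie on 2R, strain differences linked to Sox14 are a further possibility. Of 17 abundant members, 10 rose and 2 fell, but with 1 array left out only 0 to 1 fell, so that count does not settle whether the share was larger. A larger share as the whole cause was assumed to raise each member alike, and a share that raised members unequally was not tested. Against equal rises, 6 of the 17 (5 to 6 with each array left out) had a 95% interval wholly below the list's median change of 0.87. Mal-A5, for example, read -0.21 ± 0.08 and Jon65Ai 0.09 ± 0.10. Both are bright, with means of 13.34 and 14.08, so compression may have held down their changes. Jon66Ci, with a mean of 11.48, read -0.02 ± 0.16, with an upper 95% bound of 0.34. The rise was not confined to probe sets named as shared by several genes. Of the 31 members, 30 have probe sets named as specific, and 17 of these rose and 2 fell, with a median of 0.87. This met the bound set in advance against such a confined rise. A condition that sets this test aside, a need for at least 5 members with other probe sets, was added after the values were seen. With only 1 such member the types cannot be compared. Whether probe sets named as specific also hybridise to several protease genes was not tested and stays open.

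Genes changed over 4-fold could reflect sequence differences carried on the mutant second chromosome. Differences that acted only on genes of that chromosome do not account for all 202. Of these genes, 51.98% (95% Clopper-Pearson interval 44.86 to 59.04) lie on the X, 3 and 4. Whether differences on chromosome 2 changed genes on the X, 3 and 4 was not tested. An excess on chromosome 2 (97 genes, odds ratio 1.46) passed a 2-sided Fisher's exact test (p = 0.00872), which treats neighbouring genes as independent. By arm, 2R held 63 of these genes (odds ratio 1.79, adjusted p = 0.000970 over 7 exact tests), 2L 34 (0.887, adjusted p = 1) and the X 13 (0.363, adjusted p = 0.000582). The arms were not tested one by one for clustering. The pooled test was written first and was replaced by circular shifts along the genome after the counts per arm had been seen. The shifts gave a median of 78 genes and a one-sided permutation p = 0.239 (0.440 without the genes of the fixed lists), so an excess cannot be told apart from clustering of changed genes.

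The real grouping of the 6 arrays called 3577 probe sets and the highest of the other 9 splits called 0; 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. The test of RNA degradation met neither of its bounds: the 3' minus 5' difference of actin was 0.424 larger in the mutant group, and those of eIF-4a and GAPDH were 0.24 and 0.04 larger. Without the first mutant array, a reading chosen after the values were seen, the differences were 0.11, -0.03 and -0.13, in opposite directions and under the lower bound, while 2751 probe sets were still called. As this rests on leaving out 1 array, a part played by degradation stays open.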
